A study of Mus musculus with 5 samples.

How the data were processed

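RNA from mouse brain that bound to the protein MA-Brent-1 in vitro was measured on 5 Affymetrix mouse expression arrays of 45101 probe sets. MA-Brent-1 belongs to the REF/Aly family of mRNA export factors, and 2 of the sample titles call the protein REFP2. In 2 samples the RNA was eluted from the deiminated protein and in 2 from the non-deiminated protein. The remaining sample held the initial RNA without any binding, called input here. Deimination is the conversion of arginine in a protein to citrulline. 1 title calls its sample a biological repeat, and the origin of the other repeats is not given in the sources used here. Replicate numbers follow the order of the samples and pair no arrays.

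The deposited table gives the signal intensity of each probe set on a linear scale. The submitters' processing notes name MAS5, and its version is not given in the sources used here. The mean signal after trimming 2% of the probe sets at each end was 150 on every array, so each array had been scaled to a common level. No detection calls were used here. The values were not normalised further in the primary analysis.

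A pseudocount of 4.18, which is the median of all values (41.8) divided by 10, was added before taking log2. 64 control probe sets were described apart. Of the 45037 others, 34945 had 1 gene symbol, 932 had several and 9160 had none listed, and these last are unnamed here. The Entrez identifiers of 34754 matched the gene table used here, and 0 symbols changed through it. A probe set was kept if its mean log2 signal over the 5 arrays reached the 40th percentile of the non-control probe sets, which left 27022. For gene lists and named genes, the probe set with the highest mean signal stood for each gene, which gave 13055 genes.

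Differences were tested with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a trend on signal. A single model held the means of the 3 groups, with 2 residual degrees of freedom and 10.91 prior degrees of freedom. The lone input array was assumed to vary like the bound arrays. Benjamini-Hochberg adjusted p under 0.05 was the threshold, and a probe set past it is called. All p-values measure only the spread between these samples, which may be technical. Errors after ± are standard errors from limma, and intervals cover 95%.

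Up to 10 genes per direction and comparison are named by the size of the log2 difference, among called genes whose groups did not overlap. Places left over were filled by the largest moderated t among genes whose groups did not overlap, and these did not pass. In each list past its test, the 4 members with the largest moderated t in its direction are named. Alyref and the peptidylarginine deiminases are named throughout. The 28 gene lists were written from textbook knowledge, and the 26 with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01. Camera with an estimated correlation, fry, and 10000 random lists matched over 20 bins of signal were run beside it. An estimated correlation leaves camera only the 2 residual degrees of freedom, so few lists could pass that test. Not passing it is therefore no evidence that a list did not shift. fry tests whether the genes of a list move on balance one way and does not compare them with other genes. The groups, tests, lists, rule for naming genes and most alternatives were set before the data were examined.

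The number of arrays limits the precision. The model was tested on simulated data with the same group sizes, where 200 of 27022 probe sets changed in each of 10 draws. The noise was independent between probe sets and had the spread of the bound arrays, also for the input array. Differences shared by the probe sets of an array and a noisier input array were not simulated. The shares below therefore describe that simpler setting and may not hold for these data. For deiminated against non-deiminated, 6.4% of changes of 2-fold, 52.8% of 4-fold and 86.4% of 8-fold were recovered. For deiminated against input the shares were 1.8%, 29.2% and 68.4%, and for non-deiminated against input 2.6%, 31.0% and 72.2%. Alternatives covered a smaller and a larger pseudocount (1.05 and 16.7), the filter, the scaling between arrays, the variance model, array weights, blocks for the protein name, the 4 bound arrays alone and leaving out each bound array. Scaling to the hybridisation controls and a block for their level were added after the data were seen.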

Results

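The data describe which brain RNAs bound to MA-Brent-1 with and without deimination, on 2 arrays each, with 1 array of the input RNA. The median signal of all probe sets was 29.8 and 37.5 on the deiminated arrays, 30.5 and 41.4 on the non-deiminated arrays, and 102 on the input array. The hybridisation controls bioB, bioC, bioD and cre are bacterial and phage transcripts added in fixed amounts before hybridisation. Their mean over 18 probe sets was 17.04 log2 on the input array. It was 10.59 and 12.60 on the deiminated arrays and 10.08 and 13.04 on the non-deiminated arrays. The control ratio of 3' to 5' signal was 234 for beta-actin on the input array against 29.8 to 55.6 on the bound arrays. For Gapdh it was 2.71 on the input array against 17.4 to 31.9. The ratio of 234 rests on a low 5' signal of 16.7. The 3' signal exceeded the 5' signal on every array, the bound ones included, and no result below was corrected for this.

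**Figure D1:**
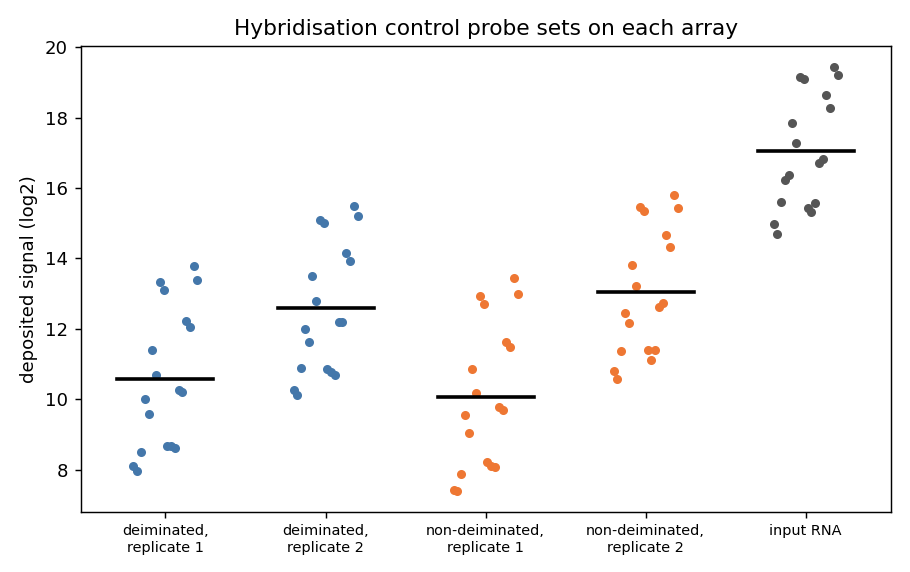
Log2 deposited signal of the 18 hybridisation control probe sets on each of the 5 arrays, with bars at the mean (blue deiminated, orange non-deiminated, grey input). The input array has a mean of 17.04, above all 4 bound arrays.

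On average, arrays of the same bound group were no more alike than arrays of different groups, with a mean r of 0.9175 against 0.928. Across the 27022 probe sets, Pearson's r was 0.938 between the deiminated arrays and 0.897 between the non-deiminated arrays. Between groups, the 4 values ran from 0.900 to 0.971, with the highest for deiminated replicate 1 and non-deiminated replicate 1. The mean r with the input array was 0.353. These are correlations across probe sets, which are not independent replicates.

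**Figure D2:**
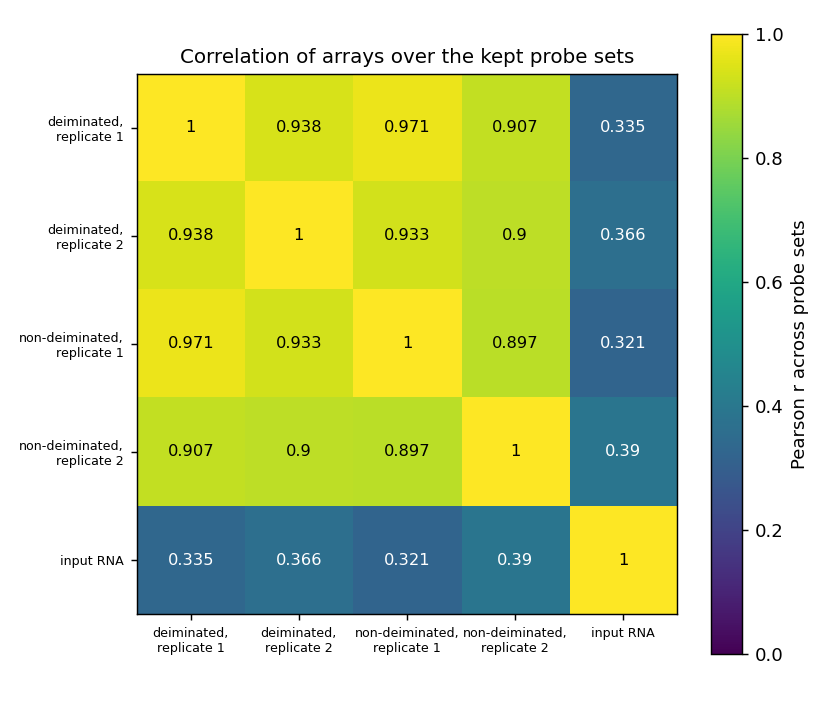
Pearson's r of log2 signal across the probe sets kept, for each pair of the 5 arrays. Bound arrays have r of 0.897 to 0.971 with one another and 0.321 to 0.390 with the input array.

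The comparison of deiminated with non-deiminated protein asks whether deimination changes which RNAs bind. No transcript of an mRNA export factor or of the deimination enzymes passed its test. Alyref, which encodes a founding member of the export factor family, had a log2 difference of -0.14 ± 0.63 (n = 2 and 2; adjusted p = 0.9999). Padi2, the main brain peptidylarginine deiminase, had -0.29 ± 0.33 and Padi1 had 0.37 ± 0.75. Padi3, Padi4 and Padi6 lay under the signal filter, and no probe set was listed for Alyref2. The 21 measured export factors had a median of -0.01 and a mean of 0.06, with 10 positive and 11 negative.

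Among single genes, limma called 0 of 27022 probe sets, and 356 had an unadjusted p under 0.05, where chance gives 1351. A count so far under chance means that the p-values ran high, so it is no evidence that the groups were alike. Each group held an array with lower and an array with higher hybridisation controls. Splitting the bound arrays by that level instead gave 3933 at an unadjusted p under 0.05, with 0 called by limma. The genes below did not pass in the comparison of the groups, and each had adjusted p = 0.9999. Xpo4, a nuclear transport receptor, had a log2 difference of 2.13 (0.80 to 3.46), and Polr1b, a subunit of RNA polymerase I, had 1.88. The zinc finger gene Zfp30 had 2.21 (0.70 to 3.72), the sodium channel subunit Scnn1a 2.14 and the matrix protease Mmp7 2.09. Nle1 had 1.95, Dok4 1.70, Fzd10os 1.69, the phosphodiesterase Pde7b 1.00 and the mitochondrial gene Mtres1 0.95 (0.26 to 1.63). In the other direction, Mroh2a had -2.59 (-4.04 to -1.14), the retinoic acid receptor Rarg -2.39, the kinase Stk35 -2.35 and Appbp2os -2.28. Cd4 had -2.05, Gtpbp6 -1.98, the protease inhibitor Serpina3n -1.95 and the glycosylation enzyme Pmm2 -1.87. The cell cycle factor E2f5 had -1.52 and the GPI anchor gene Pigu -1.33 (-2.15 to -0.51). Other probe sets of these genes had the same direction in 3 of 7 cases. Without non-deiminated replicate 1, limma called 24 probe sets, with Zfp30 at 3.38 (adjusted p = 0.0456, and 0.0456 to 1 when each bound array was left out). Without non-deiminated replicate 2 it called 2. Each of these settings leaves 1 non-deiminated array, assumed to vary like the deiminated ones.

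Groups did not overlap for 6517 probe sets (24.1%), where chance gives 33.3%. The 95% interval lay within 2-fold for 24.2% of probe sets and within 4-fold for 83.9%. Among the brightest 6756 probe sets the first share was 68.5%, so smaller differences were not detectable for most dim transcripts.

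Brain cell markers and RNA classes gave 0 called lists of 26 with camera, 1 at an unadjusted p under 0.05, 0 with an estimated correlation and 0 with fry. The nuclear long non-coding RNAs had the largest median, 0.26 over 17 genes, with 14 positive (adjusted p = 0.118, and adjusted p = 0.995 with an estimated correlation). Single arrays moved this shift, since without deiminated replicate 2 the median was 0.05 (adjusted p = 0.769), and without deiminated replicate 1 it was 0.33 and passed at adjusted p = 0.0261. Each of these leaves 1 deiminated array, assumed to vary like the others. It also passed with no filter (adjusted p = 0.033) and with the stricter filter (adjusted p = 0.0485), and its adjusted p at the preset correlation ran from 0.0261 to 0.817 over the alternatives. Its members Miat and Snhg11 had 0.70 (-0.09 to 1.49) and 0.57 (-0.10 to 1.25), and Malat1, which is retained in nuclear speckles, had 0.09 (-0.85 to 1.02). Miat and Snhg11 were chosen after their values were seen. Neuronal markers had a median of 0.12, with 16 of 25 positive, and splicing factors and hnRNPs 0.09, with 21 of 32 positive. Immediate early genes had 0.09, axon growth genes 0.07, microglia 0.07, heat shock and chaperones 0.06, synaptic transmission 0.06, choroid plexus 0.06 and red blood cells 0.06. Oligodendrocyte and dendritically localised genes had 0.01 each. Cytosolic ribosomal proteins had -0.06, with 28 of 43 negative, cytoskeleton -0.06, proteasome -0.05 and mitochondrial ribosomal proteins -0.03. Endothelial cells had -0.10, meninges -0.18 and the 5 photoreceptor genes -0.25.

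Some lists had a median, mean and test direction that differed in sign. Oxidative phosphorylation had a median of 0.01, a mean of -0.01 and a camera direction of down, and glycolysis had 0.05, -0.03 and down. Replication-dependent histones had -0.19, 0.03 and down. Export factors had a negative median with a positive mean and direction, as did astrocyte markers with a mean of 0.0048 and a median of -0.0048. Intronless genes and ion channels had medians of -0.01 and a direction of up. The only measured mitochondrially encoded transcript, ND5, had -0.29 (-1.05 to 0.46).

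**Figure D3:**
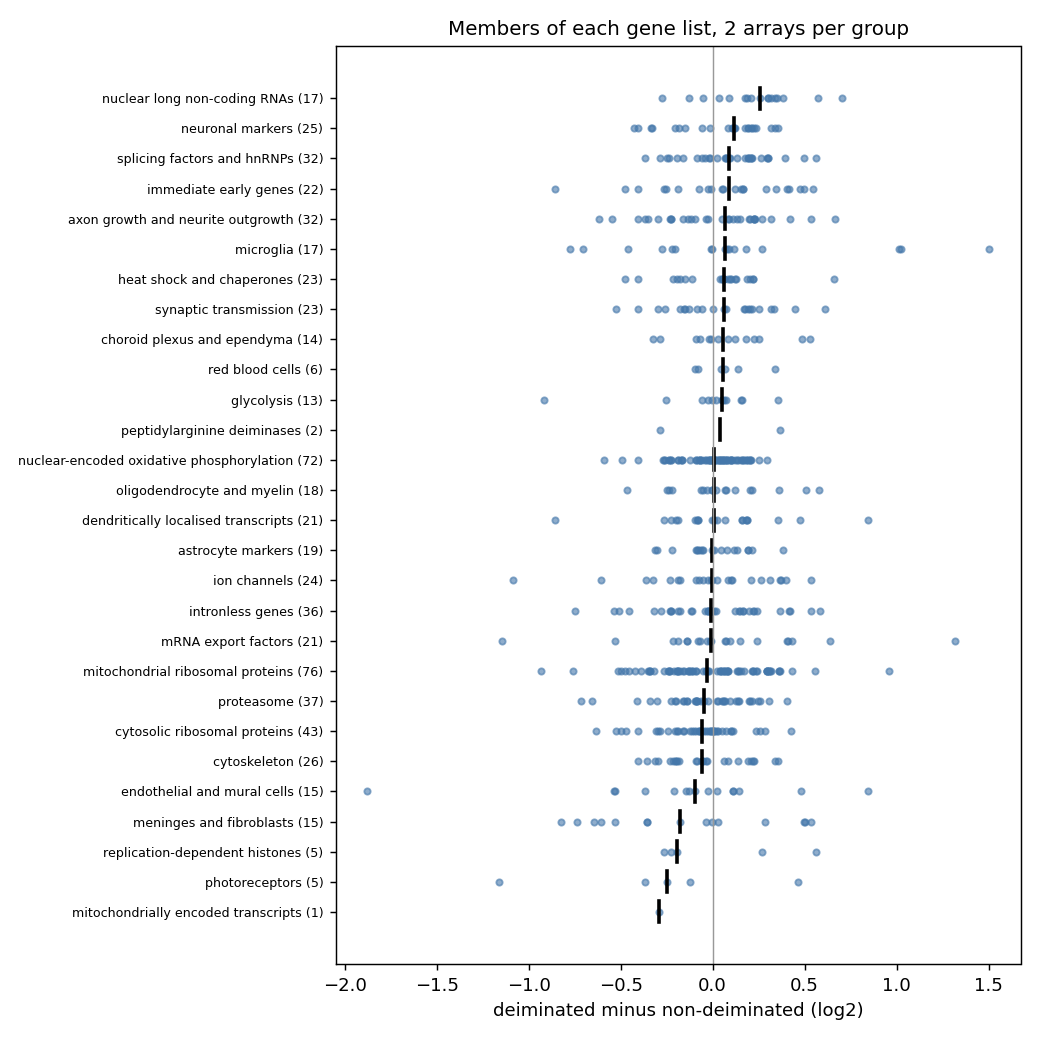
Log2 difference, deiminated minus non-deiminated, of the members of the 28 gene lists, with the median as a bar and the number of measured members in brackets. Medians lie between -0.29 for ND5 alone and 0.26 for the nuclear long non-coding RNAs.

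The comparison of deiminated-bound RNA with input asks which RNAs the protein enriched. Neuronal markers had more signal on the bound arrays than on the input array, with a median of 1.88 and 21 of 25 called higher, and 21 also when adjusted over the list alone (camera adjusted p = 1.94e-05, and adjusted p = 0.289 with an estimated correlation). The neurofilament Nefh had 5.996. The neuronal tubulin Tubb3 rose by 5.25, Snap25 of the vesicle fusion machinery by 3.22 and the vesicular transporter Slc32a1 by 2.66. Heat shock and chaperone genes had the largest median, 2.42, with 19 of 23 called higher (adjusted p = 1.94e-05, and adjusted p = 0.289 with an estimated correlation). Cct5 rose by 5.01, Hspa1a by 4.47, Cct8 by 4.26 and Dnajb1 by 3.55. Proteasome genes had a median of 1.56 (adjusted p = 0.000143, and adjusted p = 0.289 with an estimated correlation), with Psma2 at 7.11, Psma3 at 6.08, Psmc3 at 4.396 and Psmc1 at 4.06. The input side of all these calls is 1 array, whose spread was assumed equal to that of the bound arrays. On that array the r across genes of 2 probe sets of one gene was 0.0733, against 0.291 to 0.322 on the bound arrays. Many named list members had input signals near the pseudocount of 4.18, such as 8.38 for Nefh, 8.56 for Tubb3, 7.98 for Kcna2, 7.61 for Srsf2 and 9.09 for Hspa1a, so their exact differences depend on it in both comparisons with input.

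Of the 26 lists, 12 passed, 11 up and 1 down, with fry 15, and none of the 12 passed with an estimated correlation, where their adjusted p ran from 0.289 to 0.554. Few lists could pass there, since that test has only 2 residual degrees of freedom. The unadjusted camera p of glycolysis went from 0.000437 at the preset correlation to 0.0652. Its estimated correlation of -0.0509 was lower than the preset one. After quantile normalisation 1 list passed, after cyclic loess 1 and with the stricter filter 5. Among random lists of like signal, the median lay at the 99.8 percentile for heat shock, 97.0 for splicing, 96.4 for axon growth, 96.4 for the proteasome and 95.4 for neuronal markers. It lay at 91.9 for oxidative phosphorylation, 86.4 for the cytoskeleton, 85.4 for cytosolic ribosomal proteins, 74.6 for ion channels, 63.1 for astrocyte markers, 58.5 for glycolysis and 1.35 for photoreceptors. Oxidative phosphorylation had a median of 1.62 (adjusted p = 0.000138), with Atp5b at 6.45, Uqcrq at 5.55, Ndufs5 at 4.79 and Ndufa9 at 4.37. Glycolysis had 1.58 (adjusted p = 0.00162), with Pkm at 3.84, Aldoc at 2.79, Aldoa at 2.62 and Eno2 at 2.11. Axon growth genes had 1.58 (adjusted p = 0.00103), with Tubb3 at 5.25, Dpysl2 at 4.64, Ncam1 at 3.78 and Map1b at 3.76. Splicing factors and hnRNPs had 1.78 (adjusted p = 0.00103), with Hnrnpab at 5.24, Srsf2 at 4.80, Srrm2 at 4.25 and Hnrnpm at 4.24. Astrocyte markers had 1.39 (adjusted p = 0.00234), with Apoe at 6.43, Mlc1 at 5.74, Sparcl1 at 3.14 and S100b at 2.91. Cytosolic ribosomal proteins had 1.55 (adjusted p = 0.00306), with Rps19 at 4.12, Rps3a1 at 3.55, Rpl19 at 3.06 and Rps26 at 2.91. Cytoskeleton genes had 1.61 (adjusted p = 0.0124), with Nefh, Tubb3 and Map1b as above and Dstn at 4.16. Ion channels had 1.19 (adjusted p = 0.0227), with Kcna2 at 5.83, Kcnd2 at 3.21, Scn3b at 2.86 and Scn2b at 2.67. The photoreceptor genes were lower, with a median of -3.31 (adjusted p = 0.0151), and Crx, a photoreceptor transcription factor, had -4.41, Rp1 -3.34, Arr3 -3.31 and Pde6g -2.55. Only 5 of the 21 listed genes passed the signal filter, which counts the input array. With no filter the median was -2.49 (adjusted p = 0.00398, and 0.00398 to 0.229 over the alternatives at the preset correlation). The call was lost after quantile normalisation (adjusted p = 0.086) and cyclic loess (adjusted p = 0.229). With an estimated correlation it had adjusted p = 0.496. Synaptic transmission (1.20, adjusted p = 0.0887), mitochondrial ribosomal proteins (0.49, adjusted p = 0.0887) and oligodendrocyte genes (1.18, adjusted p = 0.123) did not pass. Nor did export factors (0.45), dendritically localised transcripts (0.75), nuclear long non-coding RNAs (0.49), choroid plexus (0.49), meninges (0.52), microglia (-0.05), endothelial cells (-0.44), red blood cells (-0.67), replication-dependent histones (-0.38), immediate early genes (-0.31) and intronless genes (-0.28). ND5 fell by 3.83.

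Among single genes of deiminated against input, 13925 of 27022 probe sets were called, 6736 higher and 7189 lower. Spag9, a kinase scaffold, rose by 7.59 ± 0.43 (adjusted p = 7.27e-07), and the proteasome subunit Psma2 by 7.11 ± 0.40. The 1 other kept probe set of Spag9 did not have the same direction. The carrier Slc25a46 rose by 7.02, the ubiquitin ligase subunit Fbxo22 by 6.85, the fatty acid ligase Acsl4 by 6.66 and the synaptic adhesion gene Nrxn3 by 6.64. Nop53 rose by 6.54, Rgs20 by 6.54, Ubqln1 by 6.51 and the ATP synthase subunit Atp5b by 6.45. The input signals of Spag9, Psma2, Slc25a46 and Fbxo22 were 8.003, 10.4, 7.20 and 4.49, near the pseudocount of 4.18 and far under the array's median of 102. The sizes and their order therefore depend on the pseudocount, and Spag9 had 8.02 with the smaller and 6.58 with the larger one. Naming genes by the size of the rise also favours probe sets that read low on the lone input array. There the r of 2 probe sets of one gene was only 0.0733, so these rises do not by themselves show enrichment by the protein. In the other direction, the called genes had log2 differences of -6.13 ± 0.61 for Psg28, -6.02 for the helicase gene Rtel1, -6.01 for Hsd3b3, -5.84 for Lrrc19, -5.76 for Dnajc17 and -5.72 for Bzw2. Appbp2os had -5.59, Utf1 -5.56, Spata5 -5.50 and Gm26910 -5.50. Some bound signals were about as low, with 11.5 and 9.84 for Utf1. Rtel1 had 5.08 on deiminated replicate 1 but 46.2 on replicate 2, and Appbp2os had 3.51 and 20.5. These sizes and their order therefore depend on the pseudocount too. Other probe sets of these genes had the same direction in 11 of 18 cases. Alyref had -1.35 (adjusted p = 0.155), Padi1 -2.26 (adjusted p = 0.0539) and Padi2 0.10. None of these passed, and their signs turned with the scaling. Alyref had 0.17 after quantile normalisation and 2.77 after hybridisation control scaling, Padi1 had 1.98 after the latter, and Padi2 had -0.58 after cyclic loess.

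The counts for deiminated against input rest on 1 input array and on the scaling between arrays. When each array was scaled to its hybridisation controls, a setting chosen after the data were seen, limma called 0 probe sets, 4141 had an unadjusted p under 0.05 and the median of all probe sets moved from -0.21 to 3.75. Spag9 then had 9.06 and was no longer called, and the median standard error of all probe sets went from 0.591 to 2.65. The controls also differed within the deiminated (10.59 and 12.60) and non-deiminated (10.08 and 13.04) groups, so that scaling set the arrays of a group apart. The 0 calls come with this wider spread and do not measure the effect of the input's scaling alone. Arr3 and Pde6g of the photoreceptor list then had 1.42 and 2.16, under a shift common to all probe sets. Relative to other genes the photoreceptor list was down (camera adjusted p = 0.0248), and 15 lists passed, 14 up and 1 down. Since 1 factor moves the probe sets of an array nearly alike, this comparison among genes could change little and is no separate support. Of the calls, 48.4% were higher, against 64.7% after quantile normalisation, 72.9% after median centring, 74.9% with the stricter filter and 30.8% with no filter. Without deiminated replicate 1 the count was 9226.

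The comparison of non-deiminated-bound RNA with input gave a similar list of RNAs. It uses the same 1 input array, and bound arrays of different groups had r of 0.900 to 0.971. The likeness of the lists is therefore no separate support. Neuronal markers had a median of 2.08, with 19 of 25 called higher and 22 adjusted over the list alone (camera adjusted p = 1.68e-05, and adjusted p = 0.277 with an estimated correlation). The neurofilament Nefh rose by 5.79, Tubb3 by 5.02, Snap25 by 3.01 and Slc32a1 by 2.47. Heat shock genes had a median of 2.22 (adjusted p = 1.68e-05, and adjusted p = 0.277 with an estimated correlation), with Cct5 at 4.91, Hspa1a at 4.58, Cct8 at 4.41 and Dnajb1 at 3.37. Again 12 lists passed, 11 up and 1 down, with 14 by fry and 0 under an estimated correlation, where their adjusted p ran from 0.277 to 0.562. As above, few lists could pass under an estimated correlation. After quantile normalisation 2 lists passed, after cyclic loess 1 and with the stricter filter 5. The median lay above 95% of random lists of like signal for heat shock (99.4), the proteasome (99.1), neuronal markers (98.9) and axon growth (97.4). It lay at the 92.9 percentile for the cytoskeleton, 92.3 for cytosolic ribosomal proteins, 89.8 for oxidative phosphorylation, 89.1 for splicing, 72.0 for astrocyte markers, 66.0 for glycolysis, 63.4 for ion channels and 15.5 for photoreceptors. Proteasome had 1.71 (adjusted p = 8.02e-05), oxidative phosphorylation 1.56 (adjusted p = 8.02e-05), cytosolic ribosomal proteins 1.66, glycolysis 1.61, axon growth 1.61 and cytoskeleton 1.70. Splicing factors had 1.55, astrocyte markers 1.46 and ion channels 1.04. Named members of the proteasome were Psma2 at 7.17, Psma3 at 5.82, Psmc3 at 4.33 and Psmc1 at 4.14. Those of oxidative phosphorylation were Atp5b at 6.51, Uqcrq at 5.58, Atp5c1 at 4.68 and Ndufa9 at 4.46. Among ribosomal proteins Rps19 had 4.59, Rps3a1 3.63, Rpl19 3.47 and Rpl8 2.96, and in glycolysis Pkm had 3.83, Ldha 2.86, Aldoc 2.80 and Aldoa 2.55. Axon growth genes included Tubb3, Dpysl2 at 4.42, Map1b at 3.99 and Ncam1 at 3.56, and the cytoskeleton list Nefh, Tubb3, Map1b and Dstn at 4.36. Splicing genes included Hnrnpab at 5.28, Hnrnpm at 4.61, Srrm2 at 4.05 and Hnrnpr at 3.26. Astrocyte genes included Apoe at 6.24, Mlc1 at 5.35, Sparcl1 at 2.94 and S100b at 2.69. The ion channel genes were Kcna2 at 5.30, Scn3b at 3.04, Kcnd2 at 3.004 and Clcn3 at 2.59. Photoreceptor genes had a median of -2.30 (adjusted p = 0.0236), with Crx at -4.29, Rp1 at -3.80, Pde6g at -2.30 and Arr3 at -2.15, again over 5 of 21 listed genes. That call was lost with the smaller pseudocount (adjusted p = 0.0727), quantile normalisation (adjusted p = 0.0861) and cyclic loess (adjusted p = 0.338), within a range of 0.00546 to 0.338 at the preset correlation. The lists that did not pass had medians from -0.80 for red blood cells to 1.26 for meninges. ND5 fell by 3.54.

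Of 27022 probe sets, 13635 were called, 6683 higher and 6952 lower. Spag9 rose by 7.56 ± 0.43 (adjusted p = 8.13e-07), Psma2 by 7.17, Fbxo22 by 7.02, Slc25a46 by 6.89, Ubqln1 by 6.63, Nop53 by 6.58 and Atp5b by 6.51. The RNA helicase Dhx36 rose by 6.49, Acsl4 by 6.48 and the histone chaperone gene Nap1l4 by 6.38. The input signals were again near the pseudocount, and Spag9 had 7.98 with the smaller and 6.54 with the larger one. As above, low readings on the lone input array favour such genes, and the rises do not by themselves show enrichment. Called in the other direction, Rtel1 had -6.76 ± 1.00, Lrrc19 -5.84, Dnajc17 -5.79, Bzw2 -5.62 and Utf1 -5.60. Gm31556 had -5.53, Hsd3b3 -5.35, Mamstr -5.32, Ttll10 -5.18 and Psg28 -5.17. Other probe sets of the genes named for both directions had the same direction in 9 of 13 cases, and the 1 of Spag9 did not. The bound signals of Rtel1 (6.02 and 12.2) and Utf1 (10.3 and 9.98) and the lower one of Ttll10 (2.91, against 43.1) were near the pseudocount. These sizes and their order depend on it. Padi1 fell by 2.62 (adjusted p = 0.0305), and Alyref had -1.21 (adjusted p = 0.199), with 0.26 after quantile normalisation and 2.94 after hybridisation control scaling. Padi2 had 0.39, and -0.29 after cyclic loess. For non-deiminated against input after scaling to the hybridisation controls, limma called 0 probe sets, 4190 had an unadjusted p under 0.05, the median moved from -0.19 to 3.83, and Padi1, Hsd3b3 and Psg28 had 1.76, 0.077 and 0.20. The share of calls that were higher was 49.0%, against 64.7% after quantile normalisation, 73.7% after median centring, 75.5% with the stricter filter and 31.8% with no filter. Under hybridisation control scaling 14 lists passed, all up. As for the deiminated arrays, 1 factor per array could change the lists little, and the 0 calls come with a wider spread within bound groups.

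The agreement of the bound profiles was measured against a simulation, because both comparisons share the 1 input array and this gives a correlation with no effect at all. The log2 differences had r = 0.974 across probe sets, against 0.667 (0.657 to 0.677) in 200 simulated draws of unchanged groups. Their covariance was 4.39 against 0.288. The simulation gave the input array the spread of the bound arrays, and that assumption sets the simulated values. A noisier input array would raise both with no effect at all, so the gap to the simulation is no evidence of shared binding. Of the probe sets called, 6242 were higher in both comparisons, where independence gives 1666, and 5977 were lower in both, where independence gives 1850. Independence is not the value for unchanged groups here, since any fault of the shared input array gives calls in both comparisons. The input array cannot be split, so part or all of the excess may come from it.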

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

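Of the tests in this part, those of the scaling, the hybridisation brightness, the protein name and the likeness of the bound RNA were chosen only after the result was seen.

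The hybridisation, poly-A and 18S RNA control probe sets, outside the main measurement, had far more signal on the input array than on any bound array. Mouse mRNA controls did not share this. Beta-actin 3' had 3911 on the input array against 8277 to 12622, and Gapdh 3' had 611 against 2155 to 3823. Gapdh 5' was higher on the input array, at 225 against 67.5 to 124. The hybridisation controls exceeded the highest bound array by 3.99 log2. The poly-A controls, transcripts added to the RNA before labelling, exceeded it by 3.26, and the 18S RNA probe sets by 2.86. Relative to the hybridisation controls, the 18S signal was lowest on the input array, at -2.57 log2 against -1.91 to 1.53 on the bound arrays. The excess in 18S signal therefore does not show more 18S RNA in the input.

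About as many probe sets were higher on the input array as on the bound arrays, a balance that depends on the filter and on the scaling between arrays. For deiminated against input there were 14705 lower and 6556 higher with no filter, and 1740 lower and 5180 higher with the stricter one. Weak signal of the mouse RNA on the input array may underlie the calls on that array's side. The r of 2 probe sets of one gene was 0.0733 there and 0.291 to 0.322 on the bound arrays. This met the prediction set beforehand for weak hybridisation of the input array. The hybridisation and poly-A controls, however, exceeded the highest bound array by 3.99 and 3.26 log2. The added controls were thus bright relative to other probe sets, so weak hybridisation of the whole array is not shown. The scaling of a dim input array stays open: after scaling to the hybridisation controls 0.201% of 5977 still had lower means, but that lowered the input array by 5.46 log2, more than their median difference of 2.71, so 1 factor fixed the outcome. For selective binding that holds these RNAs back, other probe sets of the 2417 genes called lower on both bound groups were examined. They lay at a median percentile of 39.6 on the input array (38.3 to 41.2), under the 44.6 of all genes. By the rule set beforehand this goes against selective binding. It is left open here on grounds that were not part of that rule. With an r of 0.0733 that array could not have shown abundance through other probe sets. Even the genes called higher reached only 53.4 on the bound arrays against 44.7 for all, under the bound in that rule.

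On average, arrays of a bound group were no closer to each other than to arrays of the other group. Splitting the 4 bound arrays by their hybridisation controls gave 3933 probe sets at an unadjusted p under 0.05, and limma called 0. Brightness of the hybridisation may play a part but stays open, since the pair with low controls had r = 0.971 and the pair with high controls 0.900, below the 0.938 of the deiminated arrays. Arrays of like control level had a mean r of 0.9357 against 0.9185 between levels, which goes with brightness. The protein name stays open, since its split gave 609, above the 359 of the split by group but below the other split, where chance gives 1351, while arrays of one name had a mean r of 0.920 against 0.926 between names, which goes against it. Whether the bound RNA was alike with and without deimination also stays open, since the interval lay within 2-fold for 24.2% of probe sets.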

How the results depend on the processing

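Scaling to the hybridisation controls and the block for their level were chosen only after the data were seen. Every alternative set beforehand was run. Replicate numbers pair no arrays. Blocks on the protein name and on the control level, each with 1 array of both bound groups, gave 0 calls by limma for deiminated against non-deiminated, with 351 and 989 at an unadjusted p under 0.05 against 356 without a block.

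For deiminated against non-deiminated, limma called 0 probe sets under all alternatives except leaving out arrays, which gave 0 to 24, with 24 without non-deiminated replicate 1 and 2 without non-deiminated replicate 2. The adjusted p of single genes lay near 1, so staying unpassed says nothing about stability. With an array left out, the sign turned in 75 of 296 values of named genes, such as Mbp (0.02 to -0.96) and Meg3 (0.35 to -0.27). The count of gene lists was 1 with no filter, 1 with the stricter filter and 0 to 1 when arrays were left out, with 1 without deiminated replicate 1.

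For deiminated against input, 13925 calls became 21261 with no filter (6556 higher, 14705 lower), 6920 with the stricter filter, which tests fewer probe sets, and 0 with hybridisation control scaling. Leaving out arrays gave 9226 to 16695, with 9226 without deiminated replicate 1. For non-deiminated against input, 13635 calls became 6800 with the stricter filter and 0 with hybridisation control scaling, and leaving out arrays gave 12512 to 15195. The cause was not tested for the change with no filter.

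The 12 gene lists of deiminated against input became 0 with an estimated correlation, 1 with quantile normalisation, 1 with cyclic loess and 5 with the stricter filter. Those of non-deiminated against input became 0, 2, 1 and 5. The fall to 0 comes with a test on 2 residual degrees of freedom, which few lists could pass. The cause of the other changes was not tested. Heat shock and chaperones passed after quantile normalisation, after cyclic loess and with the stricter filter.

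Under hybridisation control scaling all calls of single probe sets against input ended, while 15 and 14 gene lists passed, and the sign of the difference turned for Arr3 (1.42 for deiminated, 2.65 for non-deiminated) and Pde6g (2.16 and 2.47), and for non-deiminated against input also for Hsd3b3 (0.077), Psg28 (0.20) and Padi1 (1.76). It also turned for values that had not passed, Padi1 for deiminated (1.98) and Alyref for both (2.77 and 2.94). That scaling lowers the input array against the others, by its construction. It also sets the arrays of each bound group apart, and the median standard error went from 0.591 to 2.65. The loss of calls therefore does not measure the input's scaling alone. Since 1 factor moves the probe sets of an array nearly alike, the gene lists could change little. The median of all probe sets was 0.52 for deiminated against input after quantile normalisation, 0.57 after median centring and -0.24 after cyclic loess. Low signal limited the precision, with 0% of intervals within 2-fold among the dimmest 6756 probe sets and 68.5% among the brightest 6756.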

Other observations

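Tests of causes for the nuclear long non-coding RNAs in this part were all chosen only after the result was seen. Camera with an estimated correlation had been set beforehand as an alternative for all lists. Only its use as a test of deimination came after.

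The nuclear long non-coding RNAs had a median difference of 0.26 between deiminated and non-deiminated arrays. The choice of 1 probe set per gene stays open, since 65.7% of 35 other probe sets of these genes were higher, against 48.0% of all kept probe sets with 1 symbol. Brightness of the hybridisation is not favoured by its test, since the median was above 0 in both pairs of arrays with like hybridisation controls, 0.18 and 0.36, but it is not excluded, since the lower value lay at the 88.9 percentile of matched lists. Deimination itself cannot be told apart from chance, since the list did not pass in the primary analysis (camera adjusted p = 0.118 at the preset correlation). The test chosen for it, camera with an estimated correlation, gave adjusted p = 0.995. With 2 residual degrees of freedom few lists could pass that test, so it cannot decide. That test was first read without adjustment, where the value was 0.232, and the adjusted one was put in its place after that value was seen; neither passes.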
